A study of Caenorhabditis elegans with 4 samples.

How the data were processed

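Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map RNA polymerase II (Pol II) in wild-type Caenorhabditis elegans hermaphrodites of the N2 strain, the standard laboratory strain, at the last larval stage (L4). The labels describe 4 samples, namely 2 ChIP DNA samples and 2 input DNA samples, with 1 sample of each kind in either of the replicates. Input DNA is sheared chromatin that was not immunoprecipitated. The ChIP samples are labelled with the mouse monoclonal antibody 8WG16, which binds the repeated C-terminal tail of the largest Pol II subunit. Per the labels' protocols, synchronised worms were grown in liquid culture with bacteria at 20 °C and crosslinked with 2% formaldehyde. The protocol text attached to these samples speaks of embryos and of an antiserum to GFP, whereas the stage and antibody labels say L4 and 8WG16; the stage and antibody labels were followed.

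The data are 1 list of peaks with positions and a q-value for each peak. The authors called the peaks with PeakSeq, per the file headers and source field, on WormBase genome build WS190, and the list is named as combined over samples. A q-value is a p-value adjusted for the number of regions tested, and in the deposited list it compares combined ChIP with input DNA, with 1 q-value per peak and no value per sample. No version of PeakSeq, aligner or read filter is given in the sources used here. In the list itself the largest q-value was 0.00998, which fits a limit of 0.01, and no pair of neighbouring peaks lay closer than 200 bp, as would result if regions nearer than that had been joined. No strand was given for any peak. Sequencing depth is unknown here, because no read numbers were analysed, so no interval that needs depth was computed. A q-value depends on depth and on peak width as well as on enrichment, and a wider region gathers more reads.

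Peak strength was expressed as −log10 of the deposited q-value. Peak width was end minus start plus 1. Peaks were placed by their midpoint. Chromosome lengths of WS190 were not used here, and the span of each chromosome was taken as the end of its last listed peak. Densities are peaks per Mb of that span, and coverage is the length inside peaks as a percentage of it. Intervals are 95% block bootstrap intervals from 1000 resamplings. For densities, coverage and medians of single chromosomes, 250 kb blocks were drawn within each chromosome or segment. For correlations and for strength by width class, blocks that held peaks were drawn from all chromosomes of the set together. They describe how evenly the peaks of this list lie along the genome, not the variation between cultures, because combined samples leave no replicate spread to test against. No p-value between groups of worms was therefore possible. Intervals on shares of peaks are exact (Clopper-Pearson) binomial intervals and cover counting error only. Each chromosome was split into 3 equal segments, of which the middle one was taken as the centre and the outer ones as the arms. Random placement kept the peaks of each chromosome at their widths and at least 200 bp apart and was drawn 1000 times.

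The bootstrap was tested on simulated peak lists with 100 lists per setting. With a true ratio of X to autosomes of 0.6, in lists of 13032 peaks on average, the mean estimate was 0.601 and 98% of intervals held the true ratio. With a true centre-to-arm ratio of 1.5 in the same lists, the mean estimate was 1.50 and 89% of intervals held it, so those intervals can be somewhat too narrow. With no difference simulated, 96% of intervals held the true value for either ratio. Simulated density varied independently between pieces shorter than the 250 kb blocks, and fewer resamplings were drawn per list. The real density varied over longer distances, as on IV from 139 to 41 peaks in bins of 1 Mb. The simulation therefore cannot show that 250 kb blocks suffice for these data. With 1 Mb blocks the interval of the X ratio was 0.469 to 0.604. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

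The contrasts of X with the autosomes and of centres with arms, the relation of strength to width and their alternatives were fixed before the data were examined. The contrast of chromosome I with the other autosomes, the difference between the autosomal and X centre-to-arm ratios and the alternatives that keep peaks of at least 100 bp, keep the strongest decile, join peaks closer than 2000 bp or leave out a chromosome were added afterwards. The comparison of gaps between peaks with random placement was also added afterwards. The planned comparisons with gene starts, gene lists and closely spaced genes needed a gene annotation of WS190. The gene table used for names is of a later assembly, WBcel235, and coordinates of the builds were not mixed, so no peak was assigned to a gene. The rule for named genes then provided for the 10 peaks with the smallest q-values to be given by position. Tag numbers per peak were not analysed here.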

Results

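Pol II binding was mapped in L4 hermaphrodites, the larval stage at which the germ line is growing and making sperm and the last larval cuticle is replaced by the adult one. The combined list from 2 ChIP and 2 input samples held 10731 peaks. They covered 7.73 Mb, or 7.72% of the 100.1 Mb spanned by the listed peaks on the 6 nuclear chromosomes. Chromosomes I to V are the autosomes, and X is the sex chromosome, of which hermaphrodites carry a pair. All listed peaks lay on these chromosomes. The peaks were combined over samples, so the values below have no replicate error, and every interval describes the spread along the genome or counting error within this list.

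Most Pol II peaks were short, and a small number of long ones made up much of the bound length. The median width was 404 bp, with quartiles of 218 and 775 bp. The 796 peaks of at least 2 kb were 7.42% of all peaks and held 36.6% of the covered length, and 117 peaks reached 5 kb. At the other end, 970 peaks (9.04%) were narrower than 100 bp, among them 36 of a single base pair. Strength ran from a −log10 q-value of 2.00 to 303, with a median of 5.44. Wider peaks were stronger: across peaks, which are not independent replicates, Spearman's rho between width and strength was 0.69 (95% interval 0.67 to 0.70) and Pearson's r with log10 width was 0.48 (0.47 to 0.49). Within single chromosomes rho ranged from 0.65 on X to 0.78 on I.

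The 10 strongest peaks lay on chromosomes II, III, IV, V and X, and 9 of them were over 4.6 kb wide (WS190 coordinates throughout). On chromosome V they were 12551574 to 12557250 (q = 2.10e-303), 14828282 to 14837419 (q = 2.96e-303), 5838599 to 5847073 (q = 5.76e-300) and the narrower 12548602 to 12550531 (1930 bp, q = 1.54e-290). On X they were 15075722 to 15080567 (q = 1.17e-302) and 6740822 to 6745432 (q = 1.02e-284). On chromosome III they were 3863862 to 3873773 (q = 3.29e-291) and 4491012 to 4496536 (q = 3.97e-282). The others were 5333547 to 5341430 on II (q = 5.68e-296) and 13388656 to 13395605 on IV (q = 1.12e-295). The widest peak in the list, 15454 bp long, lay on chromosome II from 3955633 to 3971086 (q = 4.96e-168). What the annotation holds at these positions was not analysed here.

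How Pol II was distributed over the chromosomes was compared first. Chromosome I carried the most peaks, 2631, at 175 per Mb (95% interval 160 to 190). Chromosome III followed with 138 per Mb (127 to 148), then II with 115 (103 to 128) and IV with 109 (98.1 to 119.2). Chromosome V had 69.0 per Mb (60.4 to 77.1) and X had 62.5 (56.4 to 68.6). Against the other autosomes the density of I was 1.69-fold higher (1.53 to 1.86), and its covered length was 1.21-fold higher (1.08 to 1.36). Coverage varied less than density between chromosomes: peaks covered 9.40% of chromosome I (8.45 to 10.4), 9.12% of III (8.03 to 10.4), 8.37% of IV (7.44 to 9.30), 8.08% of II (7.08 to 9.15), 6.24% of V (5.32 to 7.15) and 5.99% of X (5.31 to 6.75). Peak width ran in the opposite order to density, from a median of 309 bp (297 to 327) on I through 367 bp on III, 394 bp on II, 442.5 bp on IV and 512.5 bp on V to 566.5 bp (527 to 598) on X.

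**Figure D1:**
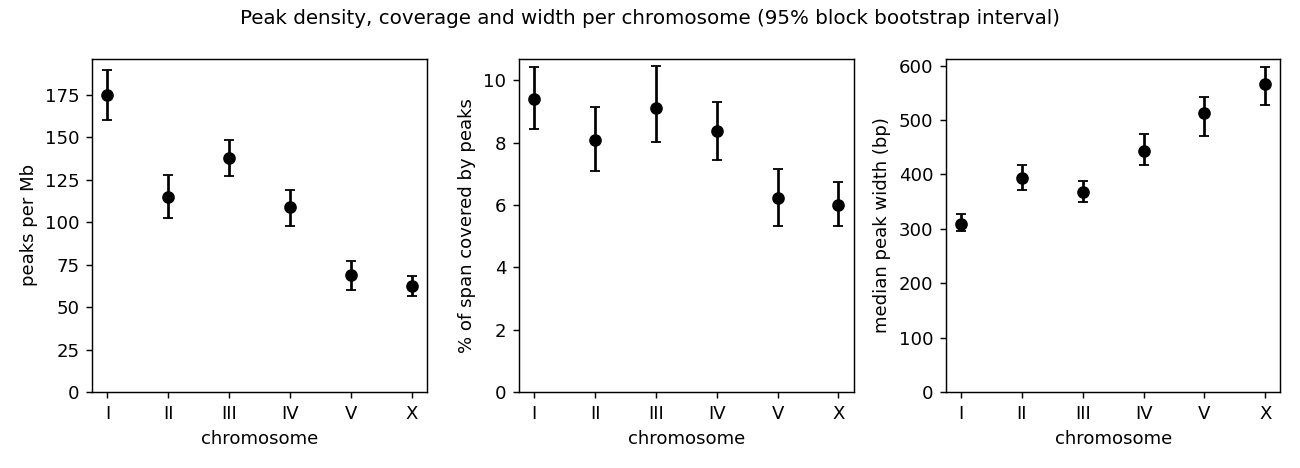
Peaks per Mb, percentage of the span covered by peaks and median peak width in bp for each chromosome; points are values from the combined list and bars are 95% block bootstrap intervals. Chromosome I has the most peaks (175 per Mb) and the narrowest (309 bp), and X the fewest (62.5 per Mb) and the widest (566.5 bp).

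The X chromosome carried fewer Pol II peaks than the autosomes as a set. In C. elegans, X is known to be largely silent in the germ line, and its transcription is reduced in hermaphrodite somatic cells by dosage compensation. X held 1108 peaks, 10.3% of the list on 17.7% of the span. Its density of 62.5 peaks per Mb against 117 on the autosomes gave a ratio of 0.536 (95% interval 0.478 to 0.592), and the ratio of covered length was 0.740 (0.644 to 0.834). The difference was not the same against every autosome. The density ratio was 0.358 (0.312 to 0.408) against I, 0.454 (0.403 to 0.517) against III, 0.545 (0.474 to 0.630) against II and 0.573 (0.502 to 0.666) against IV. Against V it was 0.907, with an interval from 0.770 to 1.08 that includes 1, and X and V could not be separated in covered length either (ratio 0.960, 0.786 to 1.16). Both values are for the full list. Among the decile of peaks with the smallest q-values, 85 lay on the 17.7 Mb of X and 160 on the 20.8 Mb of V.

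The deficit of X was deepest among peaks of high and intermediate strength. Of the decile of peaks with the smallest q-values, 7.91% lay on X (exact binomial interval 6.37 to 9.69). In decile 3 the share was 7.27% (5.79 to 8.99), and in the weakest decile it was 14.2% (12.1 to 16.4). Each decile had an upper bound below the 17.7% that X takes of the span, although these bounds treat peaks as independent and can be too narrow. The very strongest and widest peaks were too few to show whether the deficit extended to them: X held 12 of the 100 strongest (12%, 6.36 to 20.0) and 17 of the 117 peaks of at least 5 kb (14.5%, 8.70 to 22.2), and both intervals include 17.7% as well as the 10.3% that X holds of the whole list. Chromosome I, with 15.02% of the span, held 24.4% (21.9 to 27.1) of the strongest decile, 29.5% (26.8 to 32.4) of decile 3 and 16.9% (14.7 to 19.2) of the weakest. Among the very strongest and widest peaks it showed no clear excess over its span. I held 15 of the 100 strongest (8.65 to 23.5%) and 16 of the 117 peaks of at least 5 kb (13.7%, 8.02 to 21.3). Both intervals include its share of the span and lie below the 24.5% that I holds of the whole list.

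**Figure D2:**
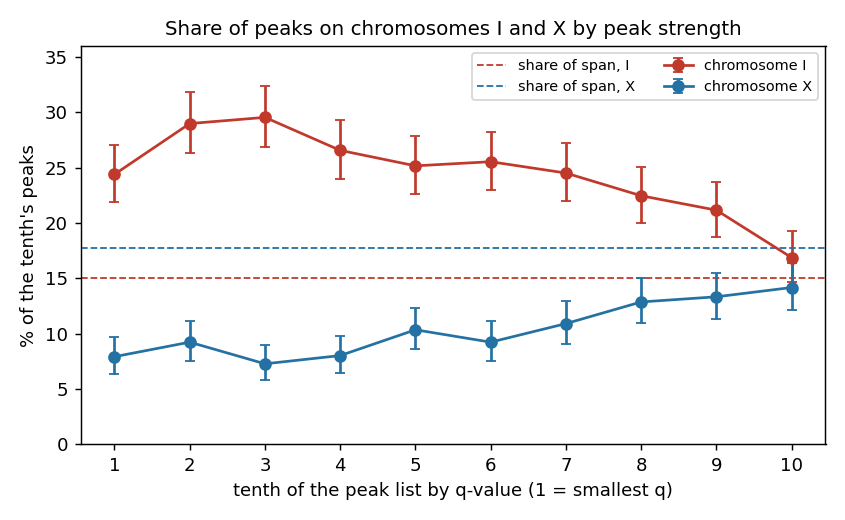
Percentage of the peaks in each decile of the list, ordered by q-value, that lie on chromosome I or X; bars are exact 95% binomial intervals and dashed lines are the chromosomes' shares of the span (15.02% and 17.7%). X rises from 7.91% in the strongest decile to 14.2% in the weakest, and stays below its share of the span.

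At equal listed width, peaks on X had weaker q-values and peaks on I stronger ones. A calling threshold that differs between chromosomes could change listed widths, so equal width need not match like regions. That was not tested, so the values do not show weaker Pol II enrichment on X. Among peaks from 250 to under 500 bp the median −log10 q-value was 7.05 (95% interval 6.57 to 7.46) on I, 5.06 (4.81 to 5.20) on II to V and 3.66 (3.46 to 3.96) on X. Among peaks from 1000 to under 2000 bp the medians were 29.5 (26.1 to 32.4), 16.6 (15.1 to 17.9) and 8.51 (6.80 to 10.7). The order I, II to V, X held in each of the 6 width classes. The intervals of X and II to V overlapped below 100 bp, and those of I and II to V overlapped from 2000 bp. Chromosomes II to V were pooled in these classes, so they do not show whether a single autosome resembles X. By decile of q-value, V lay between II and X in median width in every decile except decile 4, where V had 668 bp and X 615.5 bp. The medians on II, V and X were 1974, 2526.5 and 3211 bp in decile 1 and 846.5, 1238.5 and 1346 bp in decile 2.

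**Figure D3:**
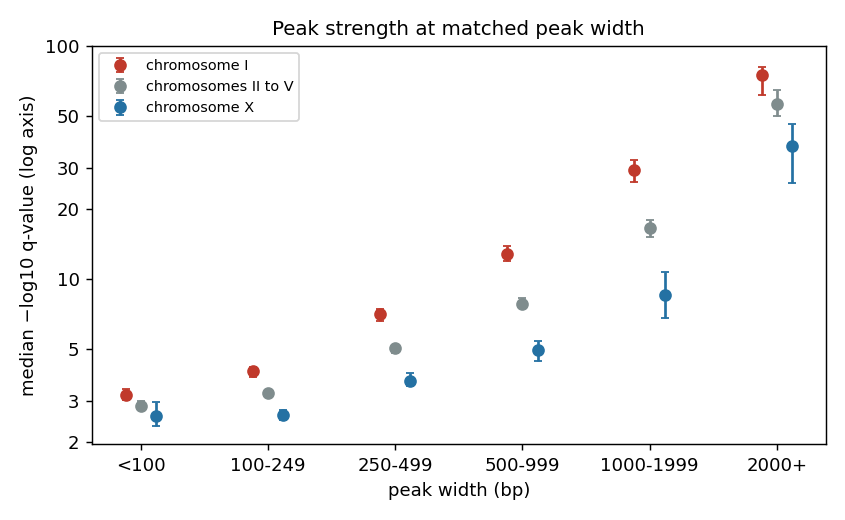
Median −log10 q-value (log axis) of peaks in 6 classes of width in bp, for chromosome I, chromosomes II to V together and X; bars are 95% block bootstrap intervals. In the class from 250 to under 500 bp the medians are 7.05, 5.06 and 3.66. Widths are as listed and can depend on the calling threshold.

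Pol II peaks were concentrated in the centres of the autosomes. The central regions of C. elegans autosomes are known to recombine little and to hold most of the conserved, broadly expressed genes, whereas the arms recombine more and are richer in repeats. With each chromosome split into 3 equal segments, the middle segments of the autosomes carried 145 peaks per Mb and the outer segments 103, a ratio of 1.41 (95% interval 1.31 to 1.52). The ratio was above 1 on each autosome, from 1.24 (1.05 to 1.42) on III through 1.35 (1.15 to 1.61) on IV, 1.42 (1.24 to 1.64) on I and 1.45 (1.19 to 1.75) on II to 1.67 (1.38 to 2.06) on V. In covered length the interval for III, 0.985 to 1.64, included 1, and those of the other autosomes did not. On X the centre held 61.8 and the arms 62.9 peaks per Mb, a ratio of 0.983 (0.801 to 1.21). The autosomal and X ratios of peak density differed by 0.52 on the log2 scale, with an interval from 0.19 to 0.83. With 1 Mb blocks the interval was 0.10 to 0.95. In covered length a difference was not established (0.35, -0.08 to 0.74).

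The arms of single autosomes were uneven. On II the left segment had 74.4 peaks per Mb and the right segment 125, and the 1 Mb bin from 1000001 to 2000000 held 34. On IV the right segment had 82.4 and the left segment 113, with 41 peaks between 16000001 and 17000000. The sparsest full bin of any chromosome was on V from 3000001 to 4000000, with 25 peaks, and the densest was on I from 9000001 to 10000000, with 255. The longest stretch without a peak, 350 kb, ran from 2250487 to 2600626 on V. The next, 338 kb, ran from 1627309 to 1964892 on X, and the one after, 289 kb, from 2905851 to 3195131 on V.

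**Figure D4:**
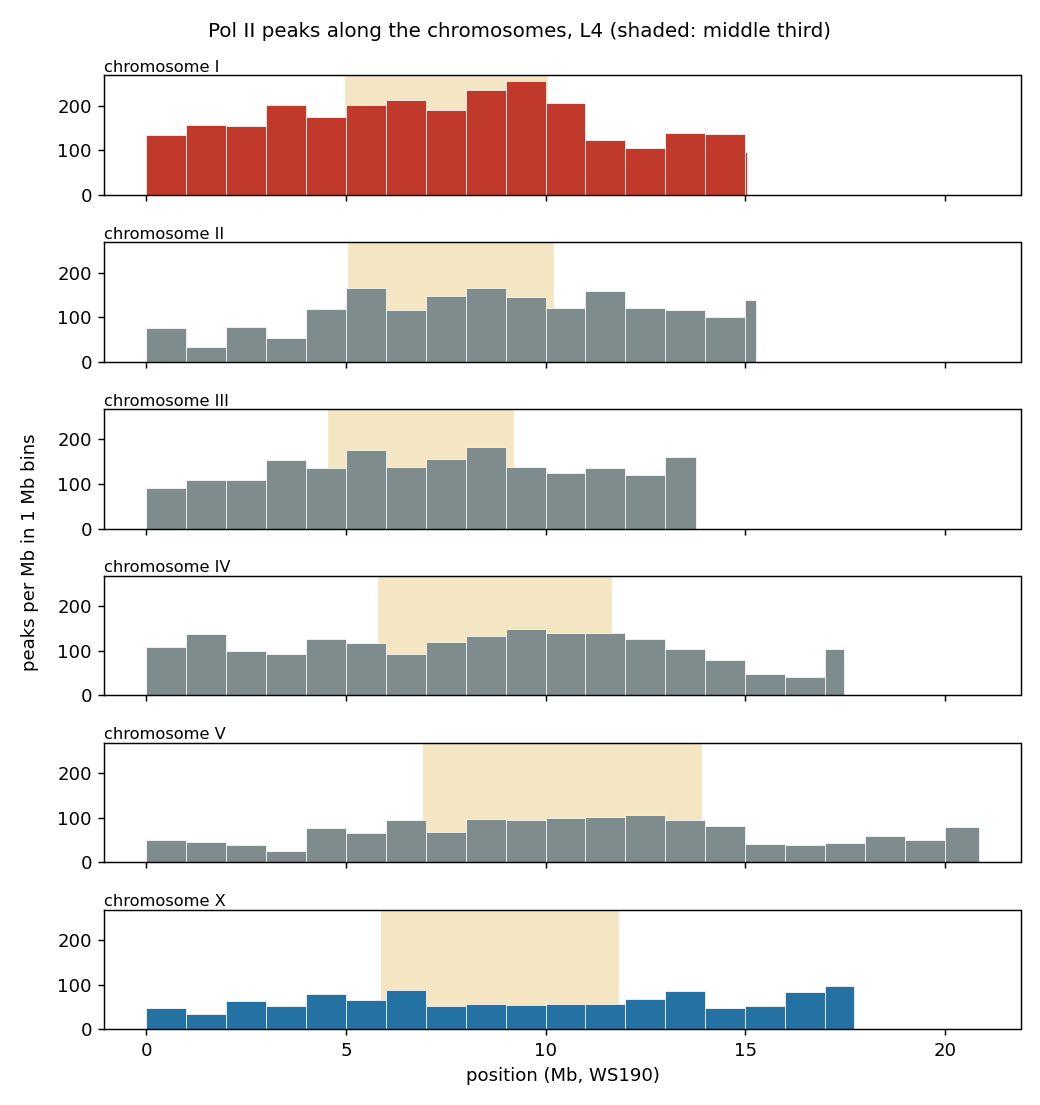
Peaks per Mb in 1 Mb bins (vertical axis) along each chromosome (horizontal axis, Mb, WS190), with the middle segment shaded. On each autosome the density is higher in the middle segment on average, although single bins outside it can exceed bins inside it. The highest bin held 255 peaks per Mb, on I. A central rise was not established on X.

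Peaks lay close together far more often than randomly placed peaks would. Enriched stretches listed as several peaks would also give short gaps, and that was not tested here. Of the 10725 gaps between neighbours, 3839 (35.8%) were under 1 kb. Random placement along the chromosomes gave 10.3% on average and at most 11.06% in 1000 draws, and placement within 1 Mb windows, which keeps the regional differences, gave 11.07% and at most 12.03%. The share of short gaps was 42.2% on I, 38.7% on IV, 35.1% on III, 34.5% on II, 29.7% on V and 26.6% on X. Such shares rise with peak density alone, and random placement was summarised only for all chromosomes together. They therefore do not rank the chromosomes by clustering.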

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

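The contrast of centre with arms in peak density differed between the autosomes and X, a comparison chosen after the ratios were seen. The log2 ratio of peak density was 0.49 on the autosomes and -0.03 on X, a difference of 0.52 with a 95% block bootstrap interval from 0.19 to 0.83. With 1 Mb blocks the interval widened to 0.10 to 0.95. A difference was not established in covered length (0.35, -0.08 to 0.74) or in the strongest decile (0.37, -0.48 to 1.205). Each of the 5 autosomes had a ratio above 1, whereas the left, middle and right segments of X held 55.0, 61.8 and 70.8 peaks per Mb.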

How the results depend on the processing

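The deficit of X, the excess in autosomal centres and the excess of chromosome I kept their direction, with intervals that exclude 1, under each alternative run. The X ratio ranged from 0.400 (strongest decile) to 0.740 (covered length) over 12 alternatives, the centre ratio from 1.34 to 1.49 over 12, and the chromosome I ratio from 1.21 (covered length) to 1.87 (the 5366 peaks with the smallest q-values) over 11. Without V the X ratio was 0.470 and without I it was 0.603. The X centre-to-arm ratio lay below 1 in the full list and above 1 in covered length (1.06, interval 0.824 to 1.39) and in the strongest decile (1.15, 0.645 to 2.04); all its intervals include 1, and the cause was not tested. The log2 difference of the autosomal and X ratios, 0.52, fell to 0.353 in covered length and 0.371 in the strongest decile, with intervals that include 0, and kept intervals above 0 in the other 5 settings. Those 5366 of the 10731 peaks were fewer by construction, while their covered length was 6.03 Mb. Joining peaks closer than 500 bp gave 8462 peaks. Without the widest peaks, above the 95th percentile (2531 bp), rho between width and strength was 0.64 rather than 0.69. Those peaks were left out by width itself, and narrowing the range of a correlated quantity can by itself lower rho. Whether this accounts for the whole drop was not tested. No paired analysis was possible because the peaks were called on combined samples, so neither replicate could be paired or left out. Comparisons at gene starts, in gene lists and between neighbouring genes, and their settings, were not run, since no annotation of build WS190 was used here. Depth, which limits the weakest and narrowest peaks most, is unknown here.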

Other observations

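The covered-length ratio of X was fixed before the data were examined. The other tests in this part were chosen after the patterns were seen, though what the strongest-decile, minimum-width, joining, leave-out and local-density tests would show was written down before their results. The comparison of widths within deciles of the list was chosen only after the values it tests were seen, and the tally of chromosome ends is not a test.

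The 10 longest stretches without a peak included 4 on V, 3 on II, 2 on X and 1 on IV, and none on I or III. Neighbouring peaks had somewhat similar strength: Spearman's rho between neighbours was 0.11 over all gaps, against at most 0.05 in 1000 shuffles within 1 Mb windows, and it was 0.21 for gaps under 500 bp and 0.04 for gaps of 10000 bp or more.

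Meiotic pairing centres are regions near 1 end of each chromosome at which homologues are known to pair (right on I, IV and V, left on II, III and X). The outer segment at that end held fewer peaks per Mb than the opposite one on 6 of 6 chromosomes, with V nearly even at a ratio of 0.980. The ratio was 0.596 (0.421 to 0.796) on II, 0.729 (0.553 to 0.961) on IV and 0.778 (0.615 to 0.981) on X, and the intervals on I, III and V included 1. The tally was 5 of 6 in covered length and after peaks closer than 2000 bp were joined, and 4 of 6 in the strongest decile. The comparison was noticed in these values, so the same list gives no test of it.

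The excess of peaks on chromosome I over the other autosomes, 1.69-fold (95% interval 1.53 to 1.86), is not confined to weak or very narrow calls. It was 1.61 (1.34 to 1.96) among the decile of peaks with the smallest q-values and 1.58 (1.43 to 1.76) among peaks of at least 100 bp. However, I held only 15 of the 100 strongest and 16 of the 117 widest peaks. Those shares are near its 15.02% of the span and below its 24.5% of the whole list. Enriched stretches cut into several listed pieces cannot account for all of it, since the ratio was still 1.43 (1.32 to 1.55) after peaks closer than 2000 bp were joined. In covered length, which does not count pieces, the ratio was smaller, 1.21 (1.08 to 1.36). Whether cutting accounts for part is not decided by the joined ratio, because joining removes more peaks from a denser chromosome with or without cutting. Regions that are as frequent on I as elsewhere but all stronger, so that more of them pass the threshold, a calling threshold that differs between chromosomes, and the gene content and transcription of I stay open and were not tested.

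The lower density of X is not confined to weak peaks with strong ones as frequent as on the autosomes, since the ratio in the strongest decile was 0.400 (0.301 to 0.517); X held 12 of the 100 strongest (6.36 to 20.0%) and 17 of the 117 widest peaks (8.70 to 22.2%), intervals that include both its 17.7% of the span and its 10.3% of the whole list, too few to tell whether the deficit extends to the very strongest. X peaks were wider, but their joining into fewer peaks does not account for the whole deficit, as the covered length was also lower at 0.740 (0.644 to 0.834). Chromosome I alone does not produce it either, the ratio without I being 0.603 (0.540 to 0.675). In the full list a low density was not confined to X, since X and V could not be separated (ratio 0.907, 0.770 to 1.08). In the strongest decile, however, X held 85 peaks on 17.7 Mb and V held 160 on 20.8 Mb, and no interval was computed for that pair. X regions that are as frequent but all weaker, so that more of them miss the threshold (which would also deepen the deficit among strong peaks), a calling threshold that differs between chromosomes, silencing of X in the germ line, dosage compensation and a difference in genes per Mb are candidate explanations that these whole-animal peaks leave open and that were not tested.

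The opposite order of peak density and peak width over the 6 chromosomes was tested next. Different mixes of strong and weak peaks do not explain the width difference between its ends, I and X. The median −log10 q-value was higher on I (6.14) than on X (4.44), and wider peaks were stronger. Mixes alone would therefore make the peaks of I wider, not narrower. The widths within deciles describe the difference but, given these values, could hardly have gone the other way. Within each decile of the list by q-value the median width on I was below that on X. The median log2 ratio over the 10 deciles was -1.07. The order of the other chromosomes did not hold in each decile, and the part of mixes in it was not tested. In decile 1 the median was 2367 bp on III against 1974 bp on II. In decile 4 it was 668 bp on V against 615.5 bp on X. Local crowding was measured by the relation between density and median width over 97 windows of 1 Mb within chromosomes. It predicts a log2 width ratio of I to X of -0.21 (-0.44 to 0.02), against the observed -0.87. Crowding at that scale thus falls short of the observed ratio. The shortfall does not exclude crowding, because shorter distances were not measured and noise in the window counts can pull the relation toward none. A calling threshold that differs between chromosomes could narrow the peaks on some of them and could also change their number per Mb. It therefore bears on the X deficit, the chromosome I excess and the order of strength at equal width as well. That, and a difference in how Pol II spreads along genes, stay open because read coverage was not analysed here.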
